A study of Ipomoea batatas with 9 samples.

How the data were processed

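The deposited table held, per the file headers, estimated counts (fractional expected counts), TPM and RPKM for each of 9 libraries and the length of each contig. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d, DESeq2 and edgeR without saying what each was used for. The contig identifiers have the form of a transcript assembly made without a genome, and the tool that made the estimated counts is not given in the sources used here. The TPM values, scaled by the authors to one constant sum per library, and the RPKM values, which the authors scaled by contig length and library total, were used here only to check the unit of the columns. The effective length in the deposited table was the contig length minus 24 for all 92382 contigs of a single transcript. The strand of the libraries is not given in the sources used here. Gene symbols, product descriptions and KEGG pathways were taken from the same table as the authors deposited them; none of the contig identifiers matched the reference gene table (0 of 110110).

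Between 18.7% and 22.6% of the values of a library were whole numbers, to within 1e-08. Estimated counts were rounded to whole numbers and tested in edgeR 4.0.16 with TMM scaling, filterByExpr, robust quasi-likelihood fits over the 9 libraries of 3 groups, and a Benjamini-Hochberg false discovery rate of 0.05, in R 4.3.3. The filter left 94808 of 110110 contigs, and 383 had no count in any library. The standard error of a log2 fold change was its size divided by the square root of the F statistic. P-values measure the spread between pooled samples and not between single roots. Reads were counted without molecular barcodes, so intervals and floors cover counting error only. A group without counts was given a floor of 3 counts per library, and groups with 1 to 9 counts in all, at or under that floor, an exact binomial 95% interval of the ratio. CPM were counts divided by the TMM-scaled library size.

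The 34 gene lists, the main test, the comparisons, the rule for named contigs, and the alternatives other than library totals alone, removal of the 100 most abundant contigs and the bound of 1% on the lower group were chosen before the data were examined. Lists were matched on product descriptions; 22 had at least 5 tested contigs and 12 had no matching description and were not analysed here. Each list was tested with camera in limma 3.58.1 at the preset correlation between contigs of 0.01, and again with the correlation estimated per list. The named contigs were, in each comparison, the 5 largest rises and the 5 largest falls among called contigs with an informative product description, a mean of at least 5 CPM in the higher group, and no overlap between the libraries of both groups. From each list, the contig with the smallest adjusted p for 4 °C against 14 °C under the same conditions was named as well, and its values were used in all 3 comparisons. After the values were seen, 14 further lists and 14 further contigs were added, which the text marks where it uses them. KEGG pathway terms with 10 to 300 tested contigs were tested for 4 °C against 14 °C with a one-sided Fisher exact test in each direction, against the 12912 tested contigs with a pathway.

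Alternatives were DESeq2 median-of-ratios scaling, library totals alone, no filter, a stricter filter, the replicate number as a block, only the 2 groups compared, the DESeq2 1.42.0 Wald test, limma-voom, a change of at least 2-fold, removal of the 100 most abundant contigs, and each library left out in turn. Overlap between both storage responses was set against 10 simulations of unchanged groups with shared controls. The main test was also tested on simulated data drawn from the mean levels of roots not stored and the fitted dispersions. Of 86331 tested contigs, 200 with at least 1 CPM were changed in the libraries at 4 °C. edgeR recovered 6.7% of 75 changed 1.5-fold, 32.8% of 61 changed 2-fold and 93.8% of 64 changed 4-fold. It called 9 unchanged contigs, and the median absolute error of the log2 fold change was 0.173. A further set raised 1.5-fold at 4 °C counted neither as changed nor as unchanged. In the data 47.8% of contigs were called for 4 °C against 14 °C, a far larger share than was changed in the simulation. With so few changed contigs the same false discovery rate needs a smaller p, so these shares do not give the recovery in the data. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads were not aligned again, and sequences of the contigs were not used here.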

Results

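Storage roots of the sweetpotato cultivar Xushu 18 (Ipomoea batatas) were profiled by RNA sequencing after 3 treatments: not stored, stored at 14 °C, and stored at 4 °C, with 85% relative humidity in both stores. Sweetpotato is a crop of warm climates whose storage roots are injured by chilling, and the series asked which genes of the root respond to low temperature. Each treatment had 3 libraries, each from a pool of 7 roots, so n = 3 for every group mean below and errors are SDs unless stated otherwise. The time in store of the sequenced roots is not given in the sources used here, so storage time and temperature are compared together against the roots that were not stored.

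The table held 110110 contigs of an assembled transcriptome, of which 39542 carried a gene symbol and 20450 a product description. A contig is named here by its identifier and, where the table gives one, its symbol. Sweetpotato is polyploid, so several contigs can come from copies of one gene, and reads of near-identical copies may have been split between them. Total estimated counts per library were 67.6e6 to 95.4e6, and a count of 0 corresponded to an upper limit of 0.031 to 0.044 CPM (counts per 1e6 counts) per library, from 3 counts and counting error only. The 100 most abundant contigs took 27.2% to 30.7% of the counts in roots not stored, 19.9% to 21.1% at 14 °C and 13.5% to 14.4% at 4 °C. Correlations of log2 CPM over 47348 contigs were 0.958 to 0.985 between libraries of one group, 0.834 to 0.89 between roots not stored and roots at 14 °C, 0.652 to 0.699 between both temperatures, and 0.61 to 0.645 between roots not stored and roots at 4 °C.

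**Figure D1:**
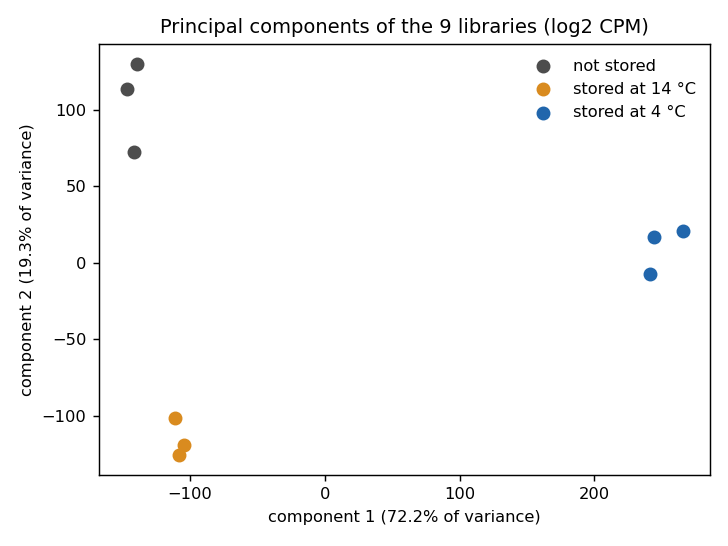
Principal components of log2 CPM over the 47348 contigs with a mean of at least 1 CPM. Each point is 1 library, coloured by treatment. Component 1 (72.2% of the variance) separates the 3 libraries at 4 °C from the other 6, and component 2 (19.3%) separates roots not stored from roots at 14 °C.

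The first comparison, 4 °C against 14 °C, set the colder store against the warmer one. As the time in store is not given, an equal time in both stores could not be checked. Roots at 4 °C held almost no transcripts of sporamin storage proteins and little of the starch synthesis list (586 ± 39.1 CPM in sum against 31700 ± 4460), and much more of several defence proteins. The 9 contigs with a sporamin symbol (GSPO), sporamin being the main storage protein of the root, summed to 156 ± 115 CPM at 4 °C and 29800 ± 4590 CPM at 14 °C, and all 9 fell. The most abundant of them, GSPO-B1 (comp1393_c34), had 78.4 ± 57.7 CPM at 4 °C against 13100 ± 2650 at 14 °C, a log2 fold change of -7.38 ± 0.84 (SE, adjusted p = 8.4e-05). AGPS1 (comp75210_c1), the small subunit of the enzyme that makes ADP-glucose for starch, had 76.6 ± 29.7 against 23300 ± 3480 CPM, a log2 fold change of -8.25 ± 0.37 (SE, adjusted p = 3.5e-08). In the other direction, PR2 (comp191_c1), a symbol used for pathogenesis-related beta-1,3-glucanases, rose from 38.3 ± 3.66 to 6380 ± 1190 CPM, and the chitinase CHIT1B (comp98986_c1) from 2.06 ± 0.0922 to 2030 ± 73.4 CPM. These 4 contigs and the GSPO list were chosen after their values were seen.

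In the edgeR quasi-likelihood test, 45355 of 94808 contigs passed a false discovery rate of 0.05, 22566 higher and 22789 lower at 4 °C. The change was at least 2-fold for 32803 of them. Among called contigs with a mean of at least 5 CPM in the higher group, 935 were higher and 584 lower by at least 4 on the log2 scale. The 3 libraries of one temperature all lay above the 3 of the other for 60.4% of contigs, where chance gives 10%.

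**Figure D2:**
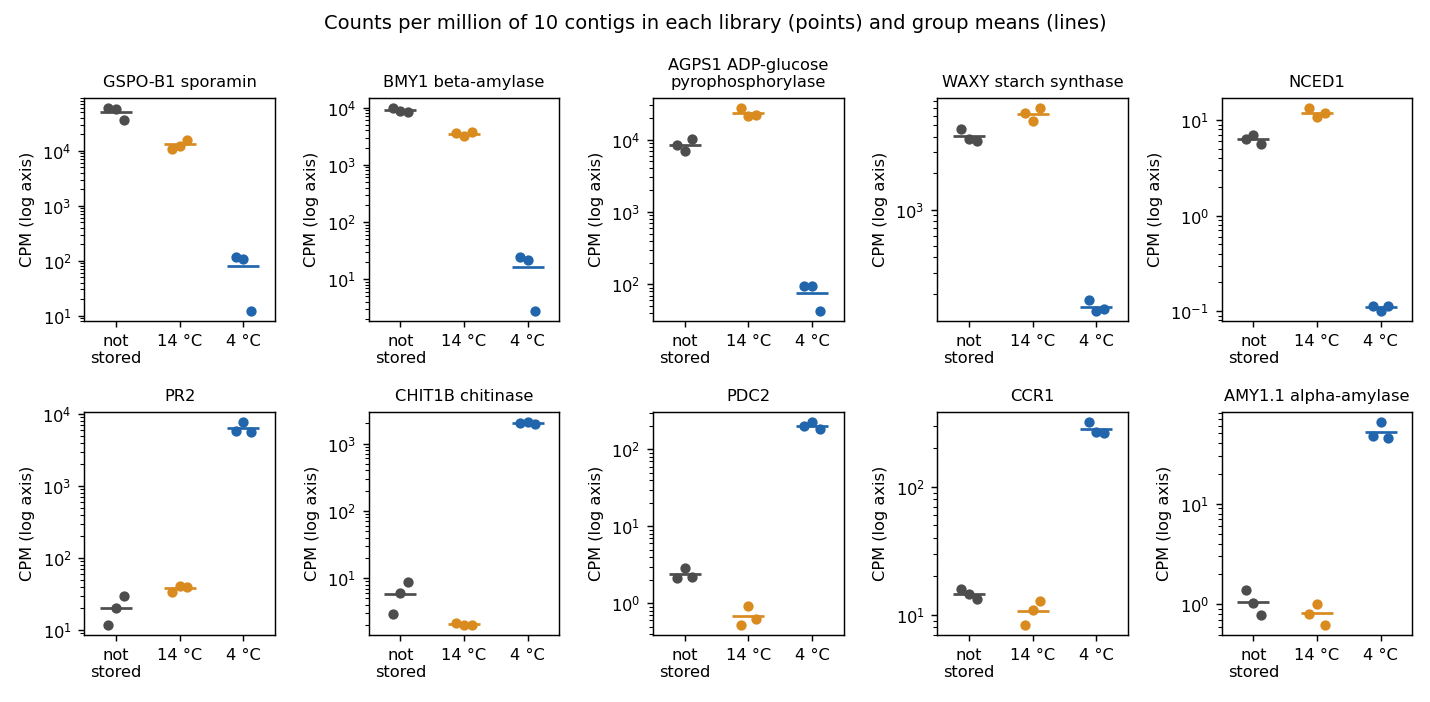
CPM on a log axis (each panel has its own scale) of 10 contigs in roots not stored, stored at 14 °C and stored at 4 °C. Points are the 3 libraries of a group and lines are group means. GSPO-B1, BMY1, AGPS1, WAXY and NCED1 were lowest at 4 °C, and PR2, CHIT1B, PDC2, CCR1 and AMY1.1 were highest there, with no overlap between the libraries at 4 °C and the other 6.

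Starch synthesis fell as a group at 4 °C. Of its 98 tested contigs, 73 fell, 8 rose and 17 did not pass the test, or 73 and 9 adjusted over the list alone. The median log2 fold change was -4.13, or -3.99 with contigs absent from one group set at their bound (camera, adjusted p = 1.2e-45, and adjusted p = 0.011 with an estimated correlation). The falls covered 44 of 61 contigs of glucose-1-phosphate adenylyltransferase, 14 of 19 of branching enzyme and 15 of 18 of starch synthase. SBE1 (comp67391_c5), a branching enzyme, dropped from 463 ± 38.2 to 14.4 ± 1.03 CPM, and WAXY (comp18538_c4), the granule-bound starch synthase, from 6240 ± 750 to 157 ± 18.5 CPM. WAXY was chosen after its values were seen, as were BMY1 in this comparison and the phosphorylase named next.

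Enzymes of starch breakdown moved in both directions: 72 of 139 contigs fell, 25 rose and 42 did not pass, or 75 and 25 adjusted over the list alone. The list was lower with a median of -0.66 (camera, adjusted p = 3.1e-06), a call lost at adjusted p = 0.1 with an estimated correlation. Beta-amylase fell in 15 of 23 contigs, starch phosphorylase in 28 of 49 and alpha-glucan, water dikinase in 11 of 16. BMY1 (comp34415_c1), the most abundant beta-amylase, had 16.1 ± 11.6 CPM at 4 °C against 3500 ± 269, and the phosphorylase comp38284_c1 had 31.8 ± 12.2 against 7800 ± 642. Alpha-amylase, which cuts starch internally, rose in 19 of 26 contigs. AMY1.1 (comp100300_c2) was at 52.3 ± 11 against 0.811 ± 0.194 CPM, a log2 fold change of 6 ± 0.26 (SE, adjusted p = 9.4e-09). Sucrose synthesis and cleavage was not called as a list, with 22 contigs higher and 17 lower of 60 (camera, adjusted p = 0.22). Its beta-fructofuranosidase (acid invertase) contigs went both ways: TIV1 comp41186_c1 dropped from 69.6 ± 9.5 to 7.39 ± 0.68 CPM, whereas TIV1 comp100247_c1 had 7.1 ± 2.73 CPM at 4 °C and no count at 14 °C, at least 200-fold higher (floor of 3 counts per library).

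The residual level of contigs that nearly vanished at 4 °C differed between the libraries there. For 29 contigs above 300 CPM in both other groups and over 50 times lower at 4 °C than at 14 °C, the 10th percentile of the level, relative to roots not stored, was 0.265% in replicate 1, 0.229% in replicate 2 and 0.0242% in replicate 3. GSPO-B1 stood at 0.225%, 0.21% and 0.0233% and BMY1 at 0.269%, 0.24% and 0.0307% in the same libraries.

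Among the 22 lists chosen beforehand, abscisic acid synthesis and signalling had the lowest median. Of 23 contigs, 21 fell and 1 rose, with the same counts adjusted over the list alone. The median was -5.34, or -4.3 with bounds (camera, adjusted p = 2.5e-21, and adjusted p = 0.011 with an estimated correlation). The falls included 14 of 15 contigs of 9-cis-epoxycarotenoid dioxygenase, which commits carotenoids to abscisic acid, and 4 of 5 of abscisic acid 8'-hydroxylase, which degrades the hormone. NCED1 (comp23975_c2) was at 0.109 ± 0.00825 CPM against 11.9 ± 1.35, a log2 fold change of -6.76 ± 0.22 (SE, adjusted p = 1.2e-09). Carotenoid synthesis was lower in 12 and higher in 2 of 27 contigs, with PSY2 (comp16323_c1), a phytoene synthase, down from 11.9 ± 1.03 to 0.898 ± 0.108 CPM. That list passed camera (adjusted p = 0.0038) but not with an estimated correlation (adjusted p = 0.11).

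Defence and phenylpropanoid lists rose. All members of the pathogenesis-related list were chitinases, enzymes that cut fungal cell walls; 31 of 38 rose and 1 fell, with the same counts adjusted over the list alone. The median was 4.12, or 3.92 with bounds (camera, adjusted p = 7e-19, and adjusted p = 0.011 with an estimated correlation). Cht2 (comp36326_c1) went from 2.67 ± 0.427 to 139 ± 13.1 CPM. General phenylpropanoid and lignin synthesis rose in 67 and fell in 20 of 109 contigs, or 69 and 23 adjusted over the list alone (median 1.64, camera adjusted p = 8.8e-14, and adjusted p = 0.052 with an estimated correlation). Phenylalanine ammonia-lyase, the entry enzyme, rose in 12 of 13 contigs, cinnamate 4-monooxygenase in 7 of 8, ferulate-5-hydroxylase in 12 of 15 and 4-coumarate-CoA ligase in 19 of 27. Cinnamoyl-CoA reductase was mixed, 11 higher and 13 lower of 34, and its member CCR1 (comp81202_c1) rose from 10.6 ± 2.22 to 284 ± 33.5 CPM. Flavonoid synthesis rose in 24 and fell in 4 of 38 contigs, or 26 and 4 adjusted over the list alone (camera, adjusted p = 2.1e-05, and adjusted p = 0.11 with an estimated correlation), including the 6'-deoxychalcone synthase comp99489_c1 at 63.1 ± 4.5 against 2.4 ± 0.352 CPM.

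Glutathione S-transferases, which conjugate reactive compounds, rose in 71 and fell in 19 of 112 contigs, or 74 and 20 adjusted over the list alone (camera, adjusted p = 1.1e-09, and adjusted p = 0.2 with an estimated correlation). GST3 (comp81843_c1) rose from 0.14 ± 0.0443 to 13.8 ± 0.62 CPM. Reactive oxygen scavenging enzymes were not called as a list, 26 higher and 21 lower of 86 (camera, adjusted p = 0.47). Among members above 5 CPM the list was called higher (median 0.28, camera adjusted p = 0.023). Glutathione reductase comp79316_c1 rose from 95.4 ± 1.98 to 539 ± 75.9 CPM. Jasmonate synthesis and signalling rose in 4 and fell in 0 of 8 contigs (camera, adjusted p = 0.021, lost at adjusted p = 0.23 with an estimated correlation and 0.16 with limma-voom). The 4 that rose were jasmonate O-methyltransferases, among them JMT (comp106138_c1) with a log2 fold change of 4.44 ± 0.18 (SE). The ethylene list held only 1-aminocyclopropane-1-carboxylate synthase contigs and was not called, 7 higher and 5 lower of 16, with a median of 1.07 against a camera direction of lower; ACS1 (comp14944_c2) fell from 14.2 ± 1.06 to 3.73 ± 0.404 CPM.

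Aquaporins, membrane water channels, fell in 48 and rose in 17 of 79 contigs, or 49 and 18 adjusted over the list alone (median -1.88, or -1.71 with bounds, camera adjusted p = 6.2e-06, and adjusted p = 0.11 with an estimated correlation). NIP5-1 (comp6592_c1) dropped from 200 ± 5.24 to 12 ± 1.41 CPM. Light-harvesting and photosystem contigs, listed as markers of green tissue, summed to 191 ± 15.6 CPM at 4 °C, 588 ± 11.5 at 14 °C and 2070 ± 387 in roots not stored; 48 of 101 fell and 7 rose at 4 °C against 14 °C (camera, adjusted p = 2.2e-09, and adjusted p = 0.2 with an estimated correlation). CAB8 (comp42879_c2) fell from 61.8 ± 2.2 to 1.43 ± 0.352 CPM. The dividing cell list consisted mostly of core histones, and 73 of 90 contigs rose and 6 fell (median 1.33, camera adjusted p = 2.2e-09, and adjusted p = 0.25 with an estimated correlation). STN7 (comp32181_c1), whose symbol and description (an aurora-type kinase) name different proteins, fell by 1.85 ± 0.11 (SE) on the log2 scale. Ribosomal proteins rose in 535 and fell in 61 of 888 contigs (median 0.8, camera adjusted p = 1.4e-08, and adjusted p = 0.5 with an estimated correlation). The rise of comp85639_c1 was 4.21 ± 0.27 (SE); its symbol APS1 and its description, ribosomal protein L10e, name different proteins.

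Heat shock proteins, nearly all of the 70 kDa and 90 kDa families, rose in 44 and fell in 12 of 83 contigs (camera, adjusted p = 2.1e-05, and adjusted p = 0.2 with an estimated correlation), with MED37C (comp98390_c1) at 32.2 ± 2.7 against 3.26 ± 0.106 CPM. Calcium sensors rose in 52 and fell in 7 of 104 contigs, 45 of those that rose being calmodulins (camera, adjusted p = 0.00031, and adjusted p = 0.44 with an estimated correlation). The calcium-dependent kinase CPK25 (comp33435_c1) fell from 516 ± 24.7 to 118 ± 2.44 CPM. Cell wall loosening and pectin degradation rose in 51 and fell in 19 of 102 contigs (camera, adjusted p = 0.004, lost at adjusted p = 0.11 with an estimated correlation and 0.093 under the stricter filter), with the pectate lyase At3g53190 (comp104748_c1) at 15.7 ± 2.17 against 1.1 ± 0.185 CPM. Proline metabolism, fatty acid desaturases, and phospholipases and lipoxygenases were not called (camera, adjusted p = 0.087, 0.63 and 0.91), although proline metabolism was with limma-voom (0.027). Within them, pyrroline-5-carboxylate reductase comp75300_c1 rose by a log2 fold change of 1.44 ± 0.19 (SE), FAD2-2 (comp14372_c1), which makes linoleic acid, dropped from 507 ± 47.6 to 60.9 ± 3.82 CPM, and phospholipase C comp102846_c1 rose from 19.1 ± 0.833 to 278 ± 15.4 CPM. Of 10 omega-3 desaturase contigs 9 rose, and of 11 omega-6 desaturase contigs 5 fell and 0 rose.

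The rule for the largest changes named contigs that were at 0 in one group. The terpene synthase comp80835_c6 (1,8-cineole synthase), the cytokinin dehydrogenase CKX9 (comp107282_c1), the calmodulin CAM-1 (comp94427_c2) and the pectinesterase PECS-2.1 (comp103876_c5) had 16.8 ± 19.2, 14 ± 0.836, 9.44 ± 5.19 and 6.96 ± 2.45 CPM at 4 °C and no count at 14 °C. They were at least 473-fold, 394-fold, 266-fold and 196-fold higher, against a floor of 3 counts per library, but the bound of the terpene synthase was 171-fold without replicate 2 at 4 °C. Its call was lost in limma-voom (adjusted p = 0.18) and with only the 2 groups compared in edgeR (adjusted p = 0.1). The phosphoenolpyruvate carboxykinase PCK (comp29010_c17) had 17 ± 2.86 CPM at 14 °C and no count at 4 °C, at least 433-fold lower (adjusted p = 0.045). Among the roots not stored only replicate 3 had it, and its call was lost when any 1 library at 4 °C or 14 °C was left out (adjusted p = 0.077 to 0.11). The light-harvesting contig comp72969_c14 had 1 count at 4 °C, a ratio of 1375 (95% counting interval 246 to 54358) between 14 °C and 4 °C, or at least 160 without replicate 1 at 4 °C. The ratio was 894 without replicate 2 and 903 without replicate 3, each from 1 count. ARA12 (comp34489_c9), a subtilisin protease, had a log2 fold change of -8.61. It had 0.724, 0.585 and 0.0635 CPM in replicates 1 to 3 at 4 °C. As for the residual levels above, replicate 3 was the lowest, so these levels are read as upper limits. NFYA9 (comp29650_c1), a CCAAT-binding factor, had 4 counts at 4 °C, a ratio of 670 (interval 262 to 2462) between 14 °C and 4 °C, or at least 293 without replicate 3 at 4 °C and 436 without replicate 2. XTH9 (comp71774_c1), a xyloglucan endotransglucosylase, had 5 counts, a ratio of 327 (interval 140 to 1009), or 215 without replicate 3 and 532 without replicate 2.

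KEGG pathway terms of the table were tested as well. Of 210 terms tested in each direction, 17 were enriched among contigs higher at 4 °C and 19 among those lower (one-sided Fisher exact test, Benjamini-Hochberg). Higher contigs held 148 of 234 in the proteasome term where 93.1 were expected (adjusted p = 3.2e-11), 116 of 177 in phenylalanine metabolism where 70.4 were expected (adjusted p = 3.1e-10), and 126 of 247 in glutathione metabolism where 98.2 were expected (adjusted p = 0.0035). Lower contigs held 111 of 237 in the plant circadian rhythm term where 46.2 were expected (adjusted p = 3.1e-19), 47 of 93 in carotenoid biosynthesis where 18.1 were expected (adjusted p = 1.2e-09) and 28 of 52 in photosynthesis antenna proteins where 10.1 were expected (adjusted p = 1.9e-06). These terms are a selection. The smallest adjusted p among higher contigs was that of the systemic lupus erythematosus term (96 of 118 where 46.9 were expected, adjusted p = 3.7e-18). Stilbenoid, diarylheptanoid and gingerol biosynthesis was enriched among lower contigs (85 of 247 where 48.2 were expected, adjusted p = 1.2e-06). Plant-pathogen interaction was not enriched among higher contigs (adjusted p = 0.11). Contigs of one gene count separately here, so these p-values may be smaller than those of a test over genes, which was not run.

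**Figure D3:**
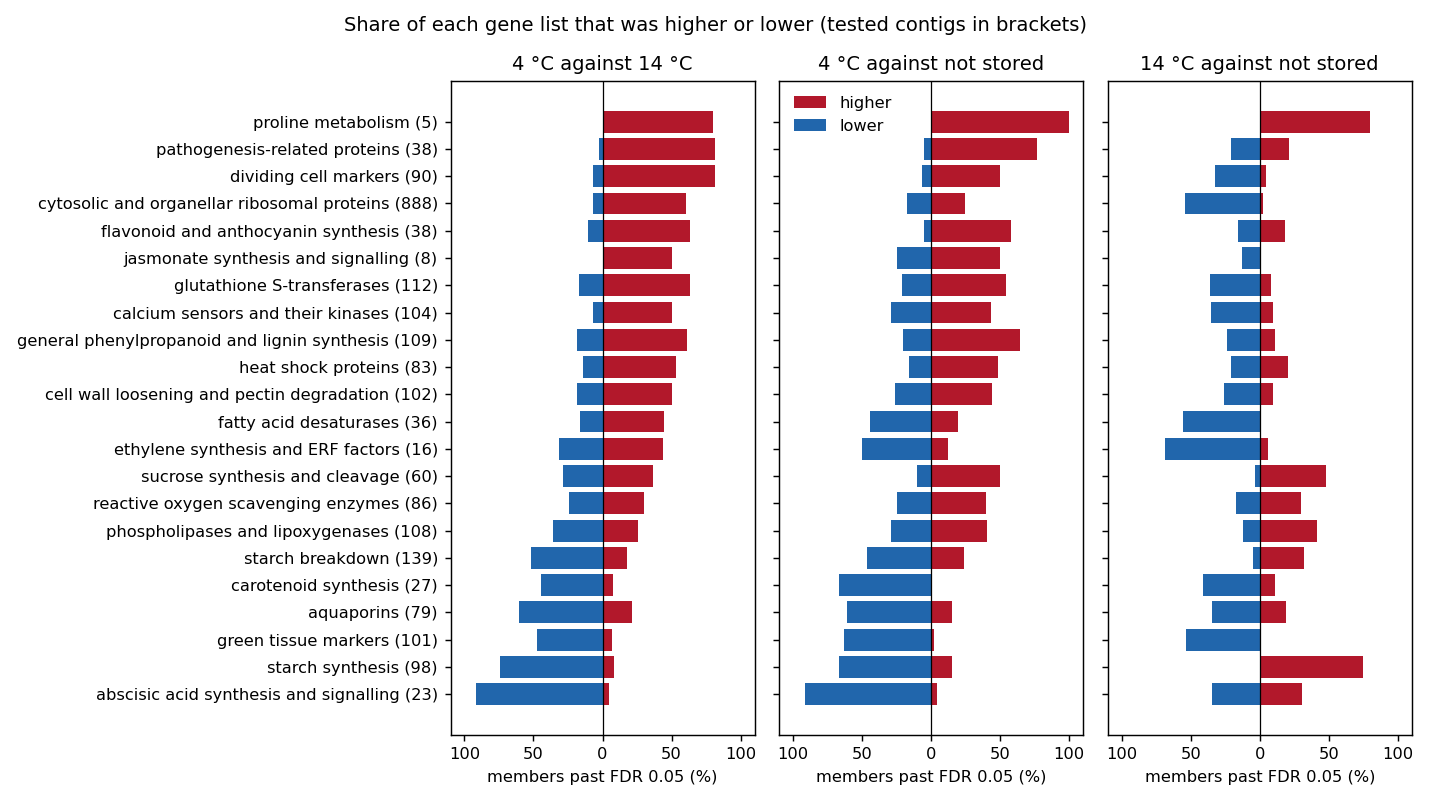
Percent of the tested contigs of each of 22 gene lists that were higher (right, red) or lower (left, blue) at a false discovery rate of 0.05, in 3 comparisons; the number of tested contigs is in brackets. Starch synthesis has 73 lower of 98 in the first panel and 73 higher of 98 in the third.

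The second comparison, 4 °C against roots not stored, combined storage with cold. Sporamin contigs fell from 94000 ± 21300 to 156 ± 115 CPM in sum, and BMY1, which the rule named here, from 8920 ± 814 to 16.1 ± 11.6 CPM, a log2 fold change of -9.12 ± 0.81 (SE, adjusted p = 1.4e-05). Among the largest falls were 3 contigs with symbols of DREB and ERF factors. DREB1C (comp62041_c1) fell from 17.2 ± 6.73 to 0.0189 ± 0.0328 CPM (4 counts, ratio 993, interval 388 to 3646, or at least 456 without replicate 1 at 4 °C, 646 without replicate 2 and 652 without replicate 3). ERF109 (comp54831_c9) fell from 12.1 ± 6.57 to 0.0178 ± 0.0155 CPM (4 counts, ratio 696, interval 272 to 2556, or 457 without replicate 3 at 4 °C). DREB1A (comp66303_c1), whose Arabidopsis namesake is a cold-response regulator, had 7.88 ± 8.49 CPM in roots not stored and no count in either store, at least 200-fold lower at 4 °C, or at least 76-fold without replicate 2 of the roots not stored. Of all 154 contigs described as such factors, a list chosen after the values were seen, 90 fell and 46 rose (camera, adjusted p = 8.8e-06, and adjusted p = 0.38 with an estimated correlation). The glucanase GGL4 (comp84208_c1) and the peroxidase comp92122_c1 were at 6.72 ± 1.39 and 6.48 ± 2.71 CPM at 4 °C. The peroxidase had no count in roots not stored (at least 177-fold higher), and GGL4 had 1 count there, a ratio of 1654 (95% counting interval 296 to 65387), or at least 182 without replicate 2 of the roots not stored and 1082 without replicate 1. PECS-2.1 had 1 count there as well (ratio 1726, interval 309 to 68221, or at least 188 without replicate 2 and 1129 without replicate 1). The counts were also low for the ethylene-forming oxidase ACO1 (comp83276_c18; 1 count, ratio 1554, interval 278 to 61412, or 705 without replicate 2 at 4 °C, at least 175 without replicate 3 of the roots not stored, and 1016 and 1027 without replicates 1 and 2, not called by limma-voom at adjusted p = 0.13) and the carbonic anhydrase NEC3 (comp82546_c1; 2 counts, ratio 821, interval 227 to 6788, or 537 without replicate 1).

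In this comparison 49812 of 94808 contigs passed in edgeR, 24644 higher and 25168 lower at 4 °C, and 37438 by at least 2-fold. The groups did not overlap for 60% of contigs (chance 10%). Starch synthesis fell in 65 and rose in 15 of 98 contigs, or 66 and 16 adjusted over the list alone (median -2.85, or -2.41 with bounds, camera adjusted p = 7e-18, and adjusted p = 0.049 with an estimated correlation). Abscisic acid contigs fell in 21 of 23 (adjusted p = 3.6e-18, and 0.023 as adjusted p with an estimated correlation). Chitinases rose in 29 and fell in 2 of 38 (adjusted p = 5.5e-16, and adjusted p = 0.023 with an estimated correlation). Green tissue markers fell in 64 and rose in 2 of 101 (median -2.77, adjusted p = 1.4e-33, and adjusted p = 0.049 with an estimated correlation). Aquaporins fell in 48 and carotenoid synthesis in 18 of their 79 and 27 contigs (adjusted p = 4.5e-09 and 2.1e-05, both at adjusted p = 0.049 with an estimated correlation). The phenylpropanoid list rose in 70 and fell in 22 of 109 (adjusted p = 5.6e-10, and adjusted p = 0.06 with an estimated correlation). Sucrose synthesis and cleavage rose in 30 and fell in 6 of 60 (adjusted p = 1e-05, and adjusted p = 0.28 with an estimated correlation), and all 5 proline contigs rose (adjusted p = 0.003, and adjusted p = 0.059 with an estimated correlation). Fatty acid desaturases fell in 16 and rose in 7 of 36 (adjusted p = 0.016, and adjusted p = 0.44 with an estimated correlation).

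Enzymes of starch breakdown fell in 65 and rose in 33 of 139 contigs at 4 °C against roots not stored (camera, adjusted p = 0.037), a call lost with an estimated correlation (adjusted p = 0.42) and in 10 other alternatives. Glutathione S-transferases rose in 61 and fell in 24 of 112 (camera, adjusted p = 0.00038, and adjusted p = 0.44 with an estimated correlation), and the dividing cell list, mostly histones, rose in 45 and fell in 6 of 90 (camera, adjusted p = 0.00015, and adjusted p = 0.44 with an estimated correlation).

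The third comparison, 14 °C against roots not stored, asked what storage did without chilling. AGPS1 rose from 8490 ± 1590 to 23300 ± 3480 CPM, a log2 fold change of 1.45 ± 0.27 (SE, adjusted p = 0.0028), and starch synthesis contigs summed to 31700 ± 4460 CPM at 14 °C against 12600 ± 1920. The clock gene APRR5 rose on both of its named contigs, comp80461_c5 from 4.45 ± 1.16 to 112 ± 6.46 CPM and comp107962_c3 from 0.648 ± 0.199 to 18.9 ± 1.16 CPM. CAB7 (comp54284_c1), a light-harvesting protein, fell from 13.5 ± 2.32 to 0.0181 ± 0.0163 CPM (5 counts, ratio 694, interval 297 to 2139, or 1097 without replicate 1 at 14 °C). ERF109 fell from 10.6 ± 6.11 to 0.0204 ± 0.0179 CPM on comp48947_c1 (5 counts, ratio 551, interval 236 to 1697, or 348 and 896 without replicates 1 and 2 at 14 °C). On comp54831_c9 it fell to 9 counts (ratio 345, interval 182 to 756, or 655 without replicate 1 at 14 °C). DREB1A had no count at 14 °C (at least 222-fold lower, or 84-fold without replicate 2 of the roots not stored). The histone H1 contig comp12407_c7, the Lon protease comp98895_c3 and the beta-glucosidase BXL1 (comp23395_c3) rose by log2 fold changes of 4.43, 3.9 and 3.85. RHM1 (comp53654_c1), a rhamnose synthesis enzyme, fell to 5 counts at 14 °C, all in replicate 3 (ratio 969, interval 415 to 2985, or at least 564 without that library and 612 and 631 without replicates 1 and 2, edgeR adjusted p = 0.002). limma-voom did not call it (adjusted p = 0.24).

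Here 29252 contigs passed in edgeR, 14337 higher and 14915 lower at 14 °C, 18104 of them by at least 2-fold, and the groups did not overlap for 44.6% (chance 10%). The direction balance depended on the scaling: with library totals alone, which shifts all contigs by a median of 0.247 on the log2 scale in this comparison, 67.9% of called contigs were higher in place of 49%. The shift was -0.15 for 4 °C against 14 °C and 0.097 for 4 °C against roots not stored. Starch synthesis rose in 73 and fell in 0 of 98 contigs, or 78 and 0 adjusted over the list alone (median 1.13, camera adjusted p = 1.4e-22, and adjusted p = 0.058 with an estimated correlation). Sucrose synthesis and cleavage rose in 29 and fell in 2 of 60 (adjusted p = 2.6e-09, and adjusted p = 0.19 with an estimated correlation), with the sucrose synthase comp63836_c2, chosen after its values were seen, at 2350 ± 392 against 905 ± 96.9 CPM. Starch breakdown rose in 45 and fell in 7 of 139 (median 0.2, adjusted p = 3e-05, and adjusted p = 0.19 with an estimated correlation).

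Green tissue markers fell in 54 and rose in 1 of 101 contigs at 14 °C (median -1.22, adjusted p = 5.2e-36, and adjusted p = 0.12 with an estimated correlation). Ribosomal proteins fell in 480 and rose in 21 of 888 (median -0.69, adjusted p = 2e-14, and adjusted p = 0.42 with an estimated correlation). Fatty acid desaturases fell in 20 and rose in 0 of 36 (adjusted p = 2e-07, and adjusted p = 0.2 with an estimated correlation), with FAD2-2 down from 976 ± 133 to 507 ± 47.6 CPM. Aminocyclopropane carboxylate synthases fell in 11 and rose in 1 of 16 (median -3.21, adjusted p = 6e-04, and adjusted p = 0.19 with an estimated correlation), but among members above 5 CPM the median was -0.07 (camera, adjusted p = 0.93), so the fall rests on contigs of low level. Calcium sensors fell in 37 and rose in 10 of 104 (adjusted p = 4.5e-06, and adjusted p = 0.39 with an estimated correlation). Chitinases, with 8 higher and 8 lower of 38, and phenylpropanoid synthesis, with 12 higher and 26 lower of 109, were not called (camera, adjusted p = 0.89 and 0.081). The abscisic acid list, 7 higher and 8 lower of 23, was not called either (adjusted p = 0.89). The phenylpropanoid list was called lower among members above 5 CPM (median -0.27, camera adjusted p = 0.023) and without replicate 2 at 4 °C (adjusted p = 0.043). No list kept its call with an estimated correlation here, and 5 of the 22 had an unadjusted p under 0.05 in that limma camera test. Sporamin contigs fell in 3 of 9 and were not called as a list (camera, adjusted p = 0.2). Their sum was nevertheless 29800 ± 4590 CPM at 14 °C against 94000 ± 21300 in roots not stored. BMY1 was at 3500 ± 269 against 8920 ± 814 CPM, without overlap between the libraries. Its log2 fold change of -1.35 ± 0.58 (SE, adjusted p = 0.11) was not called. It was called in edgeR without replicate 3 at 4 °C (adjusted p = 2.6e-05) and with only the 2 groups compared (adjusted p = 0.0001), in DESeq2 (adjusted p = 0.016) and in limma-voom (adjusted p = 0.014). The main fit takes one spread per contig over all 9 libraries, so the libraries at 4 °C enter this comparison too. GSPO-B1 was at -1.97 ± 0.66 (SE, adjusted p = 0.049). That call was lost in 7 of the 9 edgeR fits without 1 library (adjusted p = 0.064 to 0.16), with no filter (adjusted p = 0.084) and with library totals alone (adjusted p = 0.056).

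Both storage responses were set against each other over the 94808 contigs. In both stores 7760 contigs were higher and 8873 lower than in roots not stored, where independent lists of the same sizes would share 3727 and 3959. Another 3729 contigs moved in opposite directions, 1972 higher at 4 °C and lower at 14 °C and 1757 the reverse, and all 3729 also differed between both temperatures in edgeR. That last call adds little, because opposite calls against the same controls imply a larger difference between both temperatures. The log2 fold changes had a correlation of 0.4 across contigs, which are not independent replicates, against 0.5 in simulated unchanged groups that share the same 3 control libraries. Their covariance was 1.03 against 0.093 in the simulation, a difference of 0.94. In 10 simulations edgeR called 0 contigs in the same direction in both comparisons, and at most 973 at an unadjusted p under 0.05. The simulated groups held no changed contigs, so the 0 calls were nearly fixed in advance. They do not show how many shared calls the controls would add where many contigs change. The 3 libraries of roots not stored cannot be split into 2 sets of at least 2, so part of the excess of shared calls may come from the shared controls.

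**Figure D4:**
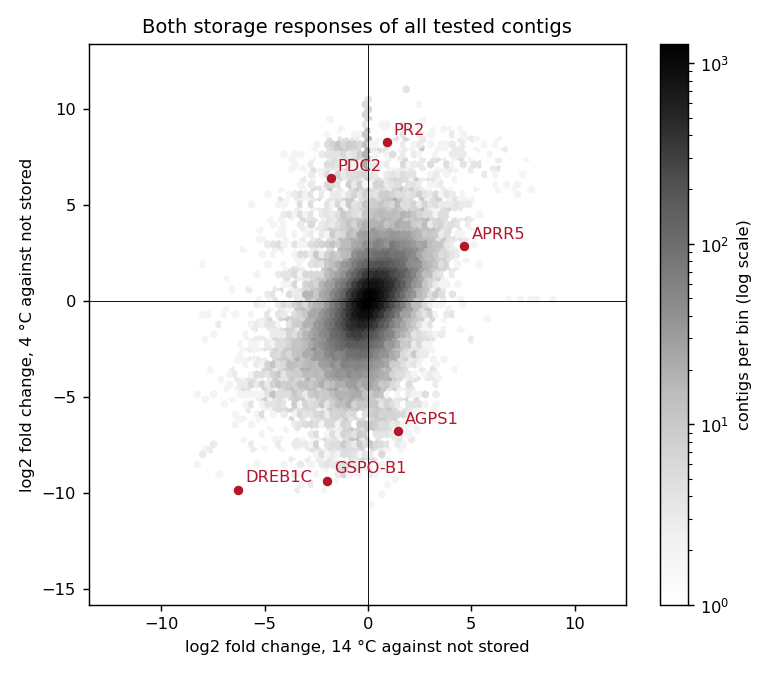
Log2 fold changes of all tested contigs against roots not stored, at 14 °C (horizontal axis) and at 4 °C (vertical axis); grey shows the number of contigs per bin on a log scale and red points are 6 named contigs. AGPS1 is higher at 14 °C (1.45) and lower at 4 °C (-6.79), and PDC2 is lower at 14 °C (-1.81) and higher at 4 °C (6.41). Contigs with no count in a group appear at their fitted value.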

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

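The tests of another species, green tissue, carry-over and low real expression were chosen only after the result was seen, as were the contigs TPM-1, AGPS1, WAXY, CHIT1B and PDC2. Each result in the next paragraph was singled out because both storage temperatures moved it in opposite directions against roots not stored and the difference between 4 °C and 14 °C itself passed the test. There were 3729 such contigs. For contigs the second condition adds little, because opposite calls against the same controls imply a larger difference between both temperatures.

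Among starch contigs, AGPS1 (-8.25 for 4 °C against 14 °C, log2), WAXY (-5.31) and SBE1 (-5.01) rose at 14 °C and fell at 4 °C. The same held for NCED1 (-6.76), the aquaporin NIP5-1 (-4.06), the kinases CPK25 (-2.13) and STN7 (-1.85), and for NFYA9 (fitted -9.27, from 4 counts at 4 °C, a ratio of 670 with an interval of 262 to 2462) and XTH9 (fitted -8.27, from 5 counts, a ratio of 327 with an interval of 140 to 1009). The reverse, lower at 14 °C and higher at 4 °C, held for CHIT1B (9.94), TPM-1 (comp76756_c1, 9.73), PDC2 (8.22), Cht2 (5.7), CCR1 (4.74), comp99489_c1 (4.71) and MED37C (3.3). CKX9 and CAM-1 were at least 394-fold and at least 266-fold higher at 4 °C than at 14 °C, where they had no count, while their falls at 14 °C rest on 15 and 43 counts in roots not stored, at least 2-fold (1-fold without replicate 1 or 2) and at least 5-fold (3-fold without replicate 2). The levels of CHIT1B without cold, 0.142%, 0.294% and 0.437% of the level at 4 °C in the libraries of roots not stored and 0.107%, 0.0982% and 0.0998% at 14 °C, were among the lowest of 25 contigs chosen for near-absence at 14 °C, and those of TPM-1 were close to them. Whether their falls at 14 °C are a response of the roots or a difference in residual reads stays open. The fall of CCR1 at 14 °C against roots not stored (adjusted p = 0.047 in edgeR) was lost under library totals alone (adjusted p = 0.34), only the 2 groups (0.08), limma-voom (0.056) and 6 of the 9 fits without 1 library (0.055 to 0.19). That of comp99489_c1 was lost under library totals alone (0.097), only the 2 groups (0.05) and without replicate 1 at 14 °C (0.059). Of the gene lists, starch synthesis (median -4.13 for 4 °C against 14 °C) and starch breakdown (-0.66) went up at 14 °C and down at 4 °C, and glutathione S-transferases (1.14) and the dividing cell markers, mostly histones (1.33), the other way. With an estimated correlation the calls against roots not stored were lost for starch breakdown (adjusted p = 0.42 at 4 °C and 0.19 at 14 °C), glutathione S-transferases (0.44 and 0.42) and dividing cell markers (0.44 and 0.63), and for starch synthesis at 14 °C (0.058). The camera call between 4 °C and 14 °C was then lost as well for starch breakdown (adjusted p = 0.1), glutathione S-transferases (0.2) and dividing cell markers (0.25), and kept for starch synthesis (0.011).

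The first pattern weighed was the near-absence of sporamin and starch enzyme contigs at 4 °C. A few abundant contigs taking most of the counts is argued against by the share of the 100 most abundant. They took 13.5% to 14.4% of the counts at 4 °C and 19.9% to 21.1% at 14 °C. The median log2 fold change of 105 vacuolar inhibitor (which include sporamin) and starch synthesis contigs outside those 100 was -4.84. It was -4.81 (SD 3.44) without the 100, both for 4 °C against 14 °C. Removing contigs of so small a share could shift fold changes only slightly, so this removal could not decide the question. Libraries from a distant species are argued against by the 598 ribosomal protein and proteasome contigs above 5 CPM. Their absolute log2 fold change had a 95th percentile of 1.97, with 0 above 5. The test cannot decide for a related species, whose reads could still be assigned to contigs of such conserved families. Green tissue is argued against by the light-harvesting and photosystem contigs, at 191 CPM (SD 15.6) at 4 °C and 588 CPM (SD 11.5) at 14 °C. A related species, sprouting without light, a different root stage or stock in the 4 °C pools, and an effect of cold itself stay open. Signs of cell division were mixed: histones were mostly higher at 4 °C, but 59 of 161 contigs of the DNA replication term were higher where 64 were expected.

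The second pattern was the residual reads of condition-specific contigs in the other condition. A small share of reads or RNA carried over between libraries would leave one shared ratio for many contigs, and low real expression of each contig in the other condition would spread the ratios. In 6 of the 6 libraries not stored or at 4 °C the 25th percentile of the ratios lay under 1.5 times the 10th, and so in 6 of the 6 also under 2 times, while the highest ratio reached 8.51%. The 29 contigs read at 4 °C were selected for a low ratio there, which narrows this spread. Those read in roots not stored were selected for near-absence at 14 °C, not for their ratio in roots not stored. Their 10th percentile was 0.145%, 0.294% and 0.436% in replicates 1 to 3 of the roots not stored. The median was 0.199%, 0.363% and 0.493%. These close values argue against a separate low level of each contig, for the lower ratios in these libraries only. At 4 °C low real expression stays open. Carry-over and a mixture of roots of another state in a pool cannot be told apart. The 10th percentile was 0.265%, 0.229% and 0.0242% in the 3 libraries at 4 °C, and levels of contigs such as GSPO-B1 at 4 °C are read here as upper limits.

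The third pattern was the number of changed contigs. For 4 °C against 14 °C, 1 of 10 splits of the 6 libraries gave as many calls as the real one (45355, highest other 0 in edgeR, or 51271 and 2577 at an unadjusted p under 0.05). For 4 °C against roots not stored, 1 of 10 did (49812, highest other 0, or 54937 and 3037), and for 14 °C against roots not stored, 1 of 10 did (29252, highest other 0, or 39729 and 12842). With 10 splits this share is never under 0.1, so the splits are too few.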

How the results depend on the processing

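The alternatives with library totals alone, without the 100 most abundant contigs, and with the lower group above 1% of the higher were chosen only after the data were seen. No call was reversed by a call in the other direction, although the median of aquaporins at 14 °C against roots not stored went from -0.53 to 0.01 among members above 5 CPM (camera, adjusted p = 0.62). Of 3740 values of lists and named contigs under an alternative, 3611 stayed as they were, called or not called, 106 lost a call and 23 gained one. Of 158 counts 153 stayed within 1.5 times. Contigs changed by at least 2-fold at 14 °C against roots not stored numbered 18104 in place of 29252, and those changed in both stores in the same direction 9763 in place of 16633, because fewer contigs pass a stricter threshold. With an estimated correlation, camera called 3, 6 and 0 of 22 lists in place of 16, 16 and 15 (4 °C against 14 °C, 4 °C against roots not stored, 14 °C against roots not stored), with 9, 8 and 5 at an unadjusted p under 0.05, and the cause was not tested. Leaving out 1 library gave 38655 to 48265, 44102 to 50447 and 20642 to 32648 changed contigs in these comparisons. Without contigs whose lower group lay at 1% or less of the higher, 43385, 47827 and 28846 calls remained. Below 3 counts per library a fold is known only as a bound or within its counting interval.

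With the replicate number as a block (replicate block), 41904, 46422 and 24558 contigs changed, and starch breakdown at 4 °C (adjusted p = 0.076) and, at 14 °C, CCR1 (0.095) and GSPO-B1 (0.064), were not called against roots not stored, while the jasmonate list was called at 4 °C (0.02). Libraries with the same number had correlations of their deviations of -0.206, -0.038 and -0.218 between 4 °C and 14 °C, and -0.267, -0.008 and -0.424 between 14 °C and roots not stored. Between 4 °C and roots not stored they were positive, at 0.175, 0.085 and 0.259, against -0.224 to 0.087 between different numbers. Because the sign differed between comparisons, the numbers were not taken as pairs.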

Other observations

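All lists and contigs in this part were chosen after the values were seen. Beyond the lists of the report, secreted peroxidases, which polymerise lignin and cell wall proteins, summed to 7430 ± 2870 CPM at 4 °C and 211 ± 4.08 CPM at 14 °C, with 50 of 72 contigs higher and 8 lower (median 6.85, or 4.99 with bounds, camera adjusted p = 1.9e-28, and adjusted p = 0.037 with an estimated correlation). Beta-1,3-glucanases rose in 11 and fell in 1 of 14 contigs, from 75.2 ± 6.91 to 10500 ± 1750 CPM in sum (camera, adjusted p = 2.3e-14, and adjusted p = 0.037 with an estimated correlation). Proteasome subunits rose in 152 and fell in 16 of 232 contigs at 4 °C against 14 °C (median 1.05, camera adjusted p = 6.7e-16, and adjusted p = 0.1 with an estimated correlation). Alcohol dehydrogenase and pyruvate decarboxylase symbols, the enzymes of ethanol fermentation, rose in 22 and fell in 3 of 30 contigs (camera, adjusted p = 6.6e-07, and adjusted p = 0.1 with an estimated correlation): ADH1 (comp95106_c1) was at 212 ± 34.1 CPM at 4 °C and PDC2 (comp106344_c1), described as an indolepyruvate decarboxylase, at 205 ± 20.8 CPM, against 7.09 and 0.685 CPM at 14 °C.

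In several families most contigs fell in store against roots not stored. AP2/ERF factors fell in 105 and rose in 5 of 154 contigs at 14 °C (median -1.48, or -1.39 with bounds, camera adjusted p = 2e-36, and adjusted p = 0.15 with an estimated correlation) and in 90 at 4 °C, where 46 rose (median -1.21, adjusted p = 0.38 with an estimated correlation). Xyloglucan endotransglucosylases, which remodel cell walls, fell in 65 and rose in 12 of 83 at 14 °C (median -4.53, or -4.4 with bounds, camera adjusted p = 6.8e-32, and adjusted p = 0.15 with an estimated correlation) and in 61 at 4 °C, where 9 rose (median -3.71, adjusted p = 0.38 with an estimated correlation). Their summed level was 1400 ± 739 CPM in roots not stored, 473 ± 25.5 at 14 °C and 1290 ± 21.5 at 4 °C, so at 4 °C most contigs fell while the sum hardly differed. At 14 °C, TIFY repressors of jasmonate signalling fell in 17 and rose in 1 of 25 (camera, adjusted p = 9.2e-12, and adjusted p = 0.15 with an estimated correlation). At 4 °C against roots not stored they rose in 10 and fell in 7 and were not called (camera, adjusted p = 0.8). DREB factors, a family with cold-response members in other plants, summed to 465 ± 205 CPM in roots not stored, 85.4 ± 2.07 at 14 °C and 95.5 ± 4.7 at 4 °C, and small heat shock proteins and the COR413 and galactinol synthase list were not called in any comparison (camera, lowest adjusted p = 0.072).

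Other contigs looked at for library composition moved too. TAR1-A (comp76979_c1), which has no product description, had 38300 ± 5720 CPM in roots not stored, 11200 ± 1910 at 14 °C and 11800 ± 292 at 4 °C (edgeR, adjusted p = 9.1e-06 and 1.8e-06 against roots not stored). Its symbol took 2.87% to 3.95% of the counts in roots not stored against 1.01% to 1.4% in store. What kind of transcript this contig holds was not tested. The actin AC58 (comp90600_c4) had 2650 ± 172, 1320 ± 272 and 366 ± 29.8 CPM, and comp15092_c1, without a symbol, 39800 ± 4010, 19000 ± 1320 and 78.3 ± 54 CPM in the same order. The fall of comp15092_c1 at 14 °C against roots not stored was not called in the main test (edgeR, adjusted p = 0.17). It was called in DESeq2 (adjusted p = 0.047), in limma-voom (0.039), and in edgeR with only the 2 groups compared (0.00043) and without replicate 3 at 4 °C (0.00012). WRKY factors rose in 79 and fell in 39 of 146 contigs at 4 °C against 14 °C (camera, adjusted p = 6.6e-07, and adjusted p = 0.19 with an estimated correlation), and NAC factors rose in 54 and fell in 17 of 101 (camera, adjusted p = 4.6e-07, and adjusted p = 0.09 with an estimated correlation). Against roots not stored, WRKY factors rose in 48 and fell in 53 at 4 °C (camera, adjusted p = 0.43). At 14 °C they rose in 17 and fell in 65 (camera, adjusted p = 7.5e-11, and adjusted p = 0.15 with an estimated correlation).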
